A study of Homo sapiens with 4 samples.

How the data were processed

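ATAC-seq libraries of OPM-2 cells were compared, with 1 library in each of 4 groups (DMSO, 1 µM ATRA, 1 µM POM and both, each for 72 h), grouped by the treatment label. Nuclei were tagged with Tn5 and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. For each library the authors deposited a list of peaks and a list of summits, called per library and not on pooled libraries. Coordinates are on hg38, per the submitters' processing notes, and the aligner, the peak caller, their settings and any shift of reads for the Tn5 cut are not given in the sources used here. Each deposited score is the whole part of 10 times the −log10 q-value in the same line. The deposited fold is the ratio of the summit pileup to the caller's background, judged from the values and the column layout. The deposited −log10 p-value and −log10 q-value belong to the summit, and the smallest −log10 q-value corresponds to a q-value of 0.05. The other deposited column gives the summit's distance from the peak start, which matched the summit lists. None of these values was scaled between libraries by any step that the sources record.

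Peaks on chromosomes 1 to 22 and X were used, which left out 5 peaks. For each comparison, all gained and all lost regions were peaks of one list that overlapped no peak of the other by 1 bp or more. Strong regions were those among the 20000 peaks of a list with the highest −log10 q-value, so that peaks near the calling threshold did not enter and both lists gave equal numbers of candidates. The overlap counts were the same with bedtools 2.31.1 in all 10 cases. Summit pileup and local background were recovered by solving the deposited fold and p-value together under a Poisson tail, which is an assumption about the caller. The recovered whole-number pileup gave the deposited −log10 p-value within 0.01 for 99.6% of DMSO, 99.7% of ATRA, 99.98% of POM and 99.8% of ATRA+POM peaks. Relative depth is the recovered background divided by the smallest peak width of the list, taken as the length over which reads were piled up, and set against DMSO. It is an estimate, since read totals were not used here. The scale between libraries is the median pileup ratio to DMSO over 42930 regions called in all lists (0.874 for ATRA, 0.397 for POM and 0.708 for ATRA+POM). A pileup expected in another library is the observed pileup times the ratio of these scales.

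Genes came from a RefSeq table of GRCh38.p14, the assembly of the hg38 coordinates, with 19974 protein-coding genes. It gives no strand, so the distance to a transcription start site planned beforehand was replaced by the distance to the gene body (limit 100 kb) and to either gene boundary (1 kb). The number of regions of a gene list was set against 10000 random lists of the same size, matched on the number of DMSO peaks per gene, and given as a percentile that describes these libraries and is no p-value. Random lists drew genes singly from the whole genome. For genes that lie in clusters the percentile can therefore overstate how unusual a list is. Merged regions of all lists were described by a log-linear model with terms for each list and for the number of lists a region is in. Intervals are Wilson intervals at 95%.

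To judge depth, libraries were simulated 20 times without a treatment effect at the recovered depths and thresholds, with Poisson and with negative binomial counts (dispersion 0.00614 from DMSO and ATRA), and again with a shift by gene number around the region measured in the shared regions. Only regions called at least once entered the simulation. The simulated lists did not keep the observed list lengths, which limits the reading of simulated counts over all regions. The code was tested on simulated data. The list comparison was checked on generic lists without the depth, threshold or counting noise of these libraries. All 200 strong gained regions planted among 60000 sites, by leaving them out of the other list, were recovered with 0 false ones. This tests the overlap code alone. Pileups were recovered at each of 19963 sites with a background of 1.5 reads. Of gene lists without extra regions, 6.5% reached the 95th percentile. For strong lost regions of POM vs DMSO, simulated libraries with 0 planted regions gave 3 and those with 200 gave 203, against at most 2 in redraws.

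The groups, the comparisons, the definitions of gained and lost, the gene lists and the rule for named genes were fixed before the data were examined. The rule named, per comparison with DMSO, the 10 strong gained and 10 strong lost regions with the highest score, the 5 genes with most strong regions in each direction, ties by score, 14 genes whatever their result, and members of a gene list with a strong region. For ATRA+POM against each single agent it named 5 regions per direction. Some genes that the rule names are not reported here. The HOX clusters and their single members over all regions, the chromosomes and gene density were singled out after their values were seen. Genes with near-identical copies elsewhere in the genome are called uncertain.

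Alternatives covered the number of strong peaks (10000 and 30000), the overlap that counts as shared (50% reciprocal, summits within 250 bp, a 500 bp margin), lists truncated to the shortest list or to their upper 75%, windows of 300 bp around summits, boundary windows of 2.5 kb, all 59084 annotated genes, and assignment within 50 kb or to gene bodies extended by 10 kb. Leaving out peaks narrower than 300 bp, and random lists matched also on peak score and gene number, were chosen after seeing the data, as were pileup ratios of strong regions between the libraries that did not select them. Transcription factor motifs were planned but not analysed here, because no genome sequence was used here. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.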

Results

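Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in OPM-2, an established human multiple myeloma line. Cells were exposed for 72 h to the vehicle DMSO, to 1 µM all-trans retinoic acid (ATRA, a ligand of the retinoic acid receptors), to 1 µM pomalidomide (POM, an immunomodulatory drug that binds cereblon), or to both agents (ATRA+POM). Each of the 4 conditions had 1 library, so no difference has a replicate check and no p-value is given. The deposited lists held 76402 peaks for DMSO, 76636 for ATRA, 69162 for POM and 85434 for ATRA+POM, covering 52.0, 51.9, 30.6 and 51.5 Mb of hg38. The background coverage recovered from the lists was 2.36 reads for DMSO, 2.36 for ATRA, 0.55 for POM and 1.51 for ATRA+POM, which places the depth of ATRA, POM and ATRA+POM at 94.1%, 33.6% and 62.7% of that of DMSO. The median read pileup at the peak summit was 30, 27, 15 and 22, and the smallest pileup called was 8, 8, 4 and 7, in the same order. The score, fold and p-value of each peak are the authors' own. Scores served to rank and match peaks, and pileups and background were recovered from the fold and p-value. Intervals below are 95% Wilson intervals and cover counting error only.

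The comparisons asked which accessible regions differed after the retinoid, after pomalidomide and after their combination in a study of t(4;14) myeloma that resists immunomodulatory drugs. A region is called strong gained when it belongs to the 20000 highest-scoring peaks of the treated library and overlaps no peak of the other list, and strong lost in the reverse case. Positions are 1-based on hg38, and a region is named by the nearest protein-coding gene body within 100 kb. A region inside a gene body is given as such, without a split into exons and introns, since the gene table used here holds neither.

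After ATRA alone, the list differed from DMSO by 9 strong gained regions (0.045% of 20000, interval 0.0237 to 0.0855%) and 15 strong lost regions (0.075%, 0.0455 to 0.124%). The highest-scoring gained region lay 13.2 kb from CBX8, a chromobox protein of Polycomb repressive complexes, at chromosome 17, 79810197 to 79810674. Its summit pileup was 103 and it was in none of the other lists. The other 8 gained regions were also called after POM and after ATRA+POM. They included regions inside CCER1 and TRPM3 and near RNF187, RPL22L1, CDH5, which encodes vascular endothelial cadherin, PLA2G4A, a cytosolic phospholipase, and NFKB1, which encodes a subunit of NF-kB (chromosome 4, 102449706 to 102450058, pileup 43). Lost regions lay inside EML1, a microtubule-associated protein gene (chromosome 14, 99793216 to 99793622, pileup 128 in DMSO), and 21 bp from MGAT5B, a glycosyltransferase gene (pileup 110 in DMSO). Both were called in POM and ATRA+POM. Further lost regions lay near HDDC2, UCHL1, a ubiquitin hydrolase gene, and MICALL1, inside ATP8A2 and CAMTA1, and at chromosome 16, 49158129 to 49158508, with no gene within 100 kb. Lost regions near GRAP (pileup 205 in DMSO) and PDXDC1 (pileup 69) are uncertain, because both genes have near-identical copies that can share reads.

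Over all peaks, 14967 ATRA peaks (19.5%) overlapped none of DMSO and 14909 DMSO peaks (19.5%) overlapped none of ATRA. Libraries simulated without a treatment effect gave a mean of 8799 gained and 17320 lost regions, against 14841 and 14767 observed when overlapping peaks of all lists were merged. The observed counts were nearly equal and the simulated ones far apart, so the simulations did not keep the list lengths. Simulated counts over all regions, here and below, are therefore no exact expectation without an effect. The strong counts were 0 and 2 with 10000 strong peaks, 89 and 111 with 30000, and 626 and 633 when absence meant no summit within 250 bp, so how few regions differed depends on the definition.

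After POM alone, 453 strong regions were gained (2.27%, 2.07 to 2.48%) and 340 were lost (1.70%, 1.53 to 1.89%). A leading gained region lay 37.2 kb from RXRG, the gene of retinoid X receptor gamma, a dimer partner of the retinoic acid receptors (chromosome 1, 165482105 to 165482485). Its pileup was 112, which at the scale between these libraries would be 282 in DMSO, where pileups from 8 upward were called. A pair of regions near GOLIM4, a Golgi membrane protein gene, was gained, at chromosome 3, 168154998 to 168155786 (pileup 101) and 167941511 to 167942139 (pileup 69). A region inside ARFGEF1, which encodes an exchange factor for ARF GTPases (chromosome 8, 67339382 to 67339787, pileup 117), was gained and was also called after ATRA. The strongest lost region lay 41 bp from POGZ, a zinc finger gene whose product binds heterochromatin protein 1 (chromosome 1, 151459069 to 151459832), with a pileup of 228 in DMSO and 90.4 projected for POM, where 4 was the smallest pileup called.

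Other gained regions named by score lay near SH3BGRL (pileup 63), inside GSTCD (63) and, with no gene within 100 kb, at chromosome 2, 145906101 to 145906746 (62). The gained region with the highest score, near TCAF1 (chromosome 7, 143836639 to 143836822, pileup 95), and those near HNRNPA1L2 (52) and at chromosome 9, 66153142 to 66153350 (53), are uncertain, as each was narrow and absent from ATRA+POM and as TCAF1 and HNRNPA1L2 have close sequence relatives. Genes with most strong gained regions were MECOM, a zinc finger transcription factor gene, with 3, and GOLIM4, TLL1, SNX18 and LPP with 2 each. Other strong lost regions lay within 1 kb of a boundary of TPTEP2-CSNK1E (pileup 191 in DMSO), UBXN6 (135) and GOLGA7B (102). Lost regions also lay inside ANKRD11, a chromatin regulator gene (237), and TNN (105), and near IER5L (105), SP2, an Sp-family transcription factor gene (94), and LTO1 (95). The genes CPAP, ALG9, GSE1 and KDM2B had 2 strong lost regions each, as did NBPF20, which is uncertain because of its many copies.

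In all, 18831 POM peaks (27.2%) overlapped none of DMSO and 27978 DMSO peaks (36.6%) overlapped none of POM. Simulation without an effect gave means of 9932 gained and 18804 lost, against 18441 and 27488 on merged regions. With 10000 strong peaks the gained and lost counts were 72 and 2, and with 30000 they were 1420 and 1849, which turned their order, while absence of a summit within 250 bp gave 1491 and 1370. Of the 453 gained regions, 125 were narrower than 300 bp. Such peaks were common in the POM list as a whole, with a lower quartile of width of 238 bp and a median of 354 bp.

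After ATRA+POM, 504 strong regions were gained (2.52%, 2.31 to 2.75%) and 173 were lost (0.865%, 0.746 to 1.00%). The region near RXRG led the gained regions (chromosome 1, 165482079 to 165482669), with a pileup of 182, or 257 at the scale of DMSO. The region inside ARFGEF1 (pileup 208) and that near GOLIM4 (142) followed. Gained regions also lay inside DCC, the netrin receptor gene (chromosome 18, 53225722 to 53226458, pileup 114), near CDH8, a neuronal cadherin gene (129), and near the olfactory receptor gene OR10R2 (150). The lost regions included positions close to boundaries of CCDC92B (257 bp from the gene, pileup 157 in DMSO), TPTEP2-CSNK1E (135 bp from a boundary, 191) and SCAMP5, a secretory membrane protein gene (134 bp from the gene, 111).

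Another 4 of the 10 gained regions named by score had no gene within 100 kb. These were at chromosome 2, 138947839 to 138948792 (pileup 130), chromosome 3, 16741563 to 16742411 (124) and 31172826 to 31173654 (110), and chromosome 4, 130738043 to 130739016 (116). GOLIM4, SNX18, IQCM, LPP and ABCA13 had 2 strong gained regions each. Other strong lost regions lay near SPRR2D (pileup 130 in DMSO), CNN1, which encodes smooth muscle calponin (121), and FLYWCH2 (113), and inside SSBP2 (94) and CACNA1A, a calcium channel gene (126). RHBDL3 had 2 strong lost regions. Lost regions near GRAP (205) and RABL2B (86) are uncertain, since both have near-identical copies. In all, 27961 ATRA+POM peaks (32.7%) overlapped none of DMSO and 19749 DMSO peaks (25.8%) overlapped none of ATRA+POM. Simulation without an effect gave means of 9298 and 17087, against 27829 and 19521 on merged regions. With all lists truncated to equal length, the order of these counts turned, with 17395 gained and 17992 lost. With 10000 strong peaks the strong counts were 78 and 7, with 30000 they were 1553 and 942, and with absence of a summit within 250 bp 1362 and 1057.

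**Figure D1:**
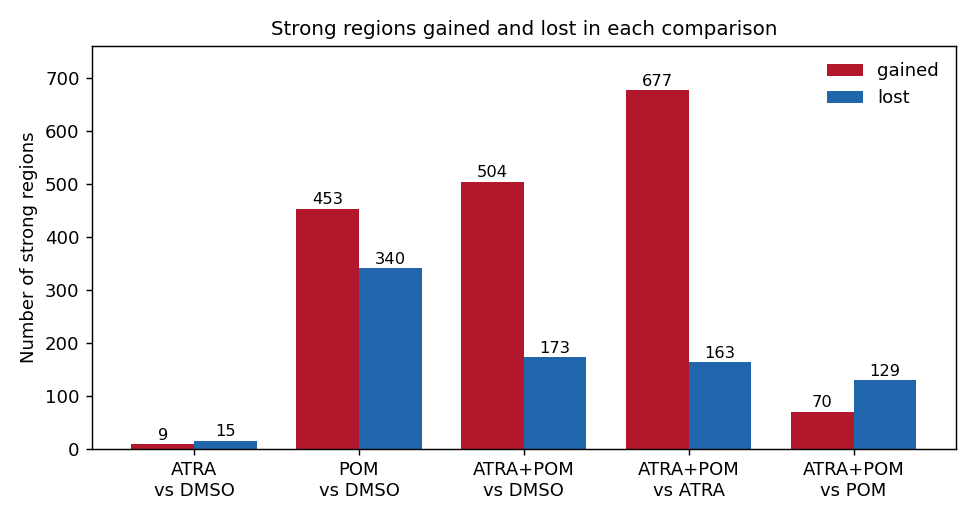
Number of strong gained (red) and strong lost (blue) regions, on the vertical axis, in each of the 5 comparisons, with the count above each bar and no error bars, since each group had 1 library. ATRA vs DMSO stands lowest with 9 and 15, and ATRA+POM vs ATRA highest with 677 gained.

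Adding POM to ATRA gave the largest number of strong gained regions of the 5 comparisons, 677 (3.39%, 3.14 to 3.64%), with 163 strong lost (0.815%, 0.699 to 0.949%). The RXRG region led again, followed by regions that DMSO also held but ATRA did not. These were at chromosome X, 94123860 to 94124811 (pileup 195), inside TENM4, a teneurin gene (185), inside CNTNAP2, a contactin-associated protein gene (172), and inside ZC3H12B (149). Lost regions lay inside TPTEP2-CSNK1E (pileup 169 in ATRA), near CCDC92B (96), inside ARHGEF11 (124), inside RABL2B (71) and at chromosome 22, 11706895 to 11707190 (70). Of the 677 gained regions, 674 (99.6%) were called after POM alone, and 267 were called in both POM and DMSO, so for these the ATRA list and not the ATRA+POM list departed from DMSO. In all, 28481 peaks (33.3%) were gained and 20308 (26.5%) lost, an order that turned to 17992 and 18408 with lists of equal length. Simulation without an effect gave means of 13350 and 12618, against 28295 and 20061 on merged regions. The strong counts were 107 and 3 with 10000 strong peaks, 1900 and 876 with 30000, and 1689 and 1135 with absence of a summit within 250 bp.

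Adding ATRA to POM gave 70 strong gained (0.350%, 0.277 to 0.442%) and 129 strong lost regions (0.645%, 0.543 to 0.766%). Gained regions lay inside TXLNB (pileup 63), 214 bp from ASB5 (60), inside TNN, a tenascin gene (71), and at chromosome 11, 11028021 to 11028518 (52) and chromosome X, 89539303 to 89539611 (47). Of these 70 regions, 66 (94.3%) were also called in DMSO and 67 (95.7%) in ATRA. The lost regions were led by those near TCAF1 (pileup 95 in POM), GRAP (65), HNRNPA1L2 (52), at chromosome 9, 66153142 to 66153350 (53), and inside UGT8, a galactosyltransferase gene (53). Of the 129 lost regions, 116 were narrower than 300 bp, leaving 13 wider ones. In all, 29933 peaks (35.0%) were gained and 12226 (17.7%) lost, or 16469 and 15035 with lists of equal length. Simulation without an effect gave means of 14694 gained and 13611 lost (range 13418 to 13763), against 29257 and 11902 on merged regions. For ATRA vs DMSO it likewise gave more lost regions (17320) than the 14767 observed, so the shortfall may lie in the simulation and is not read as a result. The strong counts were 0 and 22 with 10000 strong peaks, 608 and 452 with 30000, and 696 and 790 with absence of a summit within 250 bp.

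The effect of POM without ATRA and with ATRA was compared using libraries that the comparisons did not share. Of 453 and 677 strong gained regions, 208 were gained in both, where 5.91 were expected if the lists were independent, from the 251 and 386 of them among 16404 regions that could be gained in both. Of 340 and 163 strong lost regions, 26 were lost in both, where 1.06 were expected from 192 and 98 among 17797. Over all regions, 7496 were gained in both and 7838 lost in both, against 1797 and 2700 expected for independent lists. On merged regions these numbered 7417 and 7736, against means of 2121 and 3523 in libraries simulated without an effect, and of 4426 and 3400 when the simulation held the shift from gene-rich to gene-poor sequence. Regions gained after POM alone and lost when POM was added to ATRA numbered 666, against 162 expected for independent lists, and 623 on merged regions, below the simulated mean of 1904. Regions moving in opposite directions thus also exceeded independence. Lists of the same cells are not independent, so an excess over that expectation is no sign of an effect by itself. For ATRA without POM and with POM, 0 strong regions were gained in both and 2 were lost in both. Over all regions 2664 were gained in both, against 964 expected for independent lists, and 812 were lost in both, against 229. On merged regions the 2611 gained lay above the simulated mean of 1864, and the 783 lost lay below that of 3640 (range 3523 to 3714). Since the simulated lists did not keep the observed lengths, differences from simulated counts over all regions are not read as an effect. Against the shared DMSO list, 250 strong regions were gained after both POM and ATRA+POM, with 3.83 expected for independent lists and 0 in each of 20 simulated draws without an effect. Part of that excess may come from the DMSO library that both comparisons shared. Of the 453 regions gained after POM, 423 (93.4%, 90.7 to 95.3%) were called after ATRA+POM and 95 after ATRA. Of the 340 regions lost after POM, 285 (83.8%, 79.5 to 87.4%) were called after ATRA+POM and 338 (99.4%) after ATRA.

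Merging the peaks of all lists gave 122632 regions, of which 42930 were in all 4 lists. Regions in POM and ATRA+POM but in neither of the other lists numbered 7417, against 3218 expected from the list lengths and the number of lists a region was in and 4426 (range 4344 to 4508) simulated with the shift from gene-rich to gene-poor sequence. Regions in DMSO and ATRA alone numbered 7736, against 3528 expected and 3400 simulated with the shift. Regions in ATRA and ATRA+POM alone numbered 2611, below the 5086 expected from the lists but above the mean of 1864 (range 1798 to 1937) in libraries simulated without an effect. Regions in ATRA and POM alone numbered 623 against 2239 expected from the lists and 1904 simulated without an effect. Among 15737 regions with a pileup of at least 30 in every library, the SD of the log2 pileup ratio beyond counting error was 0.19 for DMSO and ATRA and 0.28 for POM and ATRA+POM. It was between 0.65 and 0.68 for each pair that joined a library with POM to a library without it.

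**Figure D2:**
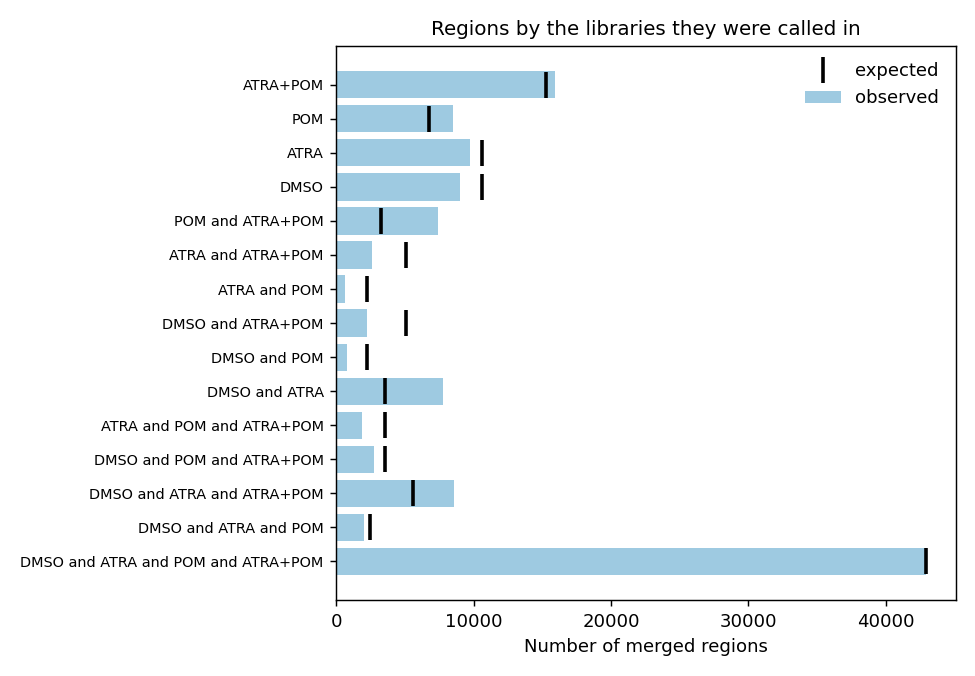
Number of merged regions (horizontal axis) called in exactly the libraries named on the vertical axis, with bars for the observed number and black ticks for the number expected from list lengths and the number of lists a region was in. POM with ATRA+POM (7417 against 3218) and DMSO with ATRA (7736 against 3528) lie above this expectation, which leaves out the shift from gene-rich to gene-poor sequence.

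Regions gained with POM lay in sequence with fewer genes, and regions lost in sequence with more genes, than the strongest peaks of the same library. Summits within 1 kb of a protein-coding gene boundary made up 3.09% (1.85 to 5.12%) of strong gained regions after POM and 1.98% (1.08 to 3.61%) after ATRA+POM, against 35.8% and 36.0% of the 20000 strongest peaks of these libraries. For strong lost regions the shares were 12.1% and 13.3% (9.02 to 19.2%), against 42.1% of the strongest DMSO peaks. Low shares near a boundary were not particular to POM. All regions gained and lost after ATRA had 3.65% and 4.86%, against 14.8% of all ATRA and 14.9% of all DMSO peaks. Strong regions gained and lost when ATRA was added to POM had 2.86% and 6.98%. Summits over 100 kb from any protein-coding gene made up 32.0% and 37.3% of the strong gained regions and 4.71% and 4.62% of the strong lost regions. The median number of genes within 1 Mb was 8 and 7 around strong gained regions, against 14 around the strongest peaks of both libraries, and 28 and 27 around strong lost regions, against 18 in DMSO. Counting all annotated genes in place of protein-coding ones raised the near-boundary shares of the gained regions to 8.61% and 7.14%.

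Shares of peaks also differed by chromosome. Gene-dense chromosome 19 held 4.03% of DMSO and 3.91% of ATRA peaks, but 2.69% of POM and 2.44% of ATRA+POM peaks. Chromosome 22 held 1.98%, 1.84%, 1.28% and 1.13%, and gene-poor chromosome 4 held 5.61%, 5.84%, 6.91% and 7.72%, in the same order. Not every chromosome followed its gene density, as the ratio of shares of POM over DMSO was 1.01 on chromosome 11, with 9.68 genes per Mb, and 0.810 on chromosome 21, with 5.12 genes per Mb. Across the 42930 regions called in all libraries, which are not independent replicates, the log2 pileup ratio of POM over DMSO fell with the number of genes within 1 Mb, with a Spearman rank correlation of -0.47. Its median was -0.86 in the fifth of regions with at most 6 genes and -1.92 in the fifth with at least 30. The correlation was -0.51 for ATRA+POM over ATRA, -0.09 for ATRA over DMSO and -0.13 for ATRA+POM over POM.

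**Figure D3:**
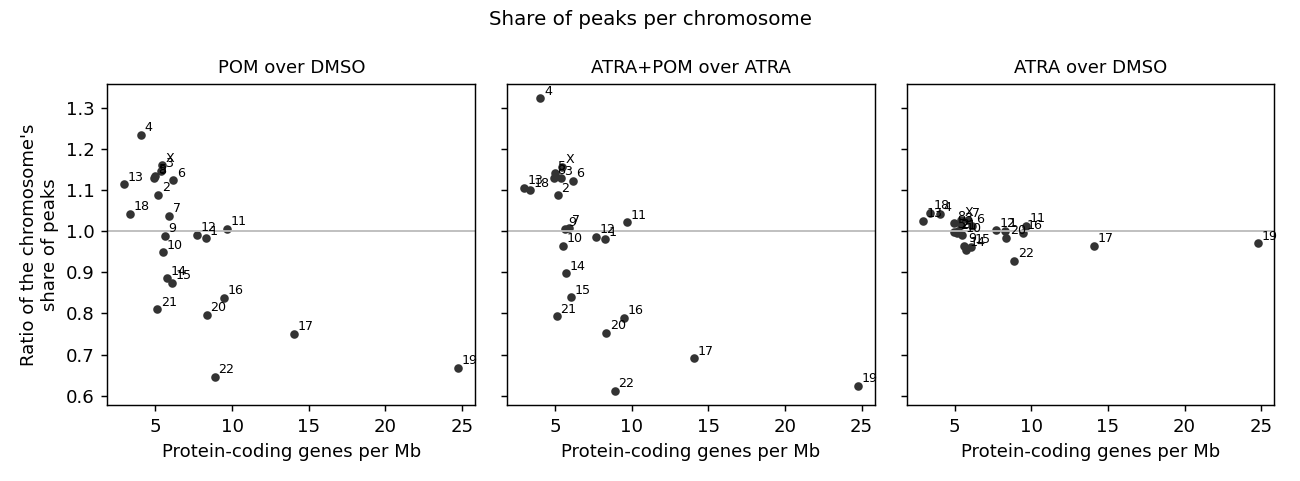
Ratio between libraries of the share of peaks on a chromosome (vertical axis) against protein-coding genes per Mb of that chromosome (horizontal axis), with 1 labelled point per chromosome and a line at a ratio of 1. Chromosome 19 lies at 0.668 for POM over DMSO and 0.624 for ATRA+POM over ATRA, while for ATRA over DMSO all chromosomes lie between 0.928 and 1.04.

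None of the 14 genes named in advance, which cover retinoid signalling, cereblon and its targets and the t(4;14) genes, had a strong gained or lost region in any comparison. RARB, the gene of retinoic acid receptor beta, had 21 assigned peaks in DMSO, 16 in ATRA, 28 in POM and 29 in ATRA+POM. Against DMSO, 8 of the 28 RARB peaks were gained after POM and 9 of the 29 after ATRA+POM, while ATRA gained 2 and lost 7. Over all peaks, 27.2% were gained after POM and 32.7% after ATRA+POM, so these gains lay near the general share. After ATRA, 19.5% of all peaks were gained and 19.5% lost. RARA had 6, 6, 4 and 5 peaks and RARG 4, 4, 3 and 3, in the order DMSO, ATRA, POM and ATRA+POM. The retinoic acid hydroxylase genes CYP26A1 and CYP26B1 had 6, 5, 6 and 6 and 4, 4, 2 and 2, and DHRS3, a retinal reductase gene, had 3, 1, 4 and 3. CD38, a surface target of antibody therapy in myeloma, had 5, 5, 3 and 6. CRBN, which encodes cereblon, had 3, 3, 3 and 6, and its target genes IKZF1 and IKZF3 had 11, 10, 9 and 12 and 8, 8, 5 and 8. IRF4 had 10, 11, 8 and 8 peaks and MYC 6, 8, 6 and 9. NSD2 and FGFR3, the genes at the t(4;14) breakpoint, had 13, 11, 8 and 7 and 5, 5, 2 and 5.

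Among 20 gene lists fixed in advance, strong regions fell on few members. Retinoic acid genes had 1 strong gained region after POM and 1 after ATRA+POM, both that near RXRG, at the 54.4th percentile of random lists in each case, and after ATRA+POM a lost region near CEBPE, a granulocyte transcription factor gene (76.3rd). A gained region near NFKB1 put the NF-kB list at the 99.5th percentile after ATRA, a value that rests on this region alone, 51.4 kb from the gene. With assignment within 50 kb the list had 0 such regions and stood at the 49.6th percentile. The region was called in every list but DMSO, and NFKB1 also had a strong gained region after POM (pileup 28). Of the interferon-stimulated genes, SAMD9L had a strong gained region after POM and after ATRA+POM. CD24 had a gained region after POM, and the death receptor gene FAS a lost region after POM and ATRA+POM. After POM, strong lost regions lay near IKZF4, an Ikaros-family gene of the cereblon list (pileup 76 in DMSO), WNT10A (64), FOS, an AP-1 subunit gene (84), and CREBBP, a histone acetyltransferase gene (121). After ATRA+POM, strong gained regions lay near CD40 (56), TCF7L1 (55), DUSP6, a phosphatase gene of MAP kinase feedback (56), and NSD1 (68), and a strong lost region near TFRC, the transferrin receptor gene (75). When POM was added to ATRA, SMAD3, CD86 and YWHAZ also had strong gained regions, and when ATRA was added to POM, LUM did while IFI44 and TFRC lost 1 each. Only 4 of 200 values of a list in a comparison and direction reached the 95th percentile.

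Over all regions, the list of 21 genes of the HOXA and HOXB clusters stood out. Of 30 DMSO peaks assigned to these genes, 17 (99.7th percentile) were absent after POM and 15 (99.8th) after ATRA+POM, against 6 (76.0th) after ATRA. Random lists drew scattered genes while these are neighbours, so the percentiles can overstate how unusual the losses are. The HOXB cluster, at chromosome 17, 48528526 to 48728750, held 21 peaks in DMSO, 16 in ATRA, 10 in POM and 9 in ATRA+POM. HOXA held 8, 10, 6 and 7. The losses lay mostly in HOXB, where 13 of 21 DMSO peaks were absent after POM and 11 after ATRA+POM. In HOXA, 3 of 8 and 1 of 8 were absent, against 36.6% and 25.8% of all DMSO peaks. The clusters outside the list were HOXC, with 13, 12, 6 and 10 peaks, and HOXD, with 9, 11, 9 and 8. A peak outside the HOXB cluster, assigned to HOXB1 within the 100 kb limit, was strong lost after POM and ATRA+POM, with a pileup of 55 in DMSO. When random lists were matched also on peak score and gene number around the gene, a matching added after the data were seen, the HOX percentiles were 96.4 and 97.0. Monocyte and granulocyte genes lost 31 of 53 peaks after POM (99.7th, 86.0th with the added matching) and 22 after ATRA+POM (97.1st, 54.7th with the added matching). After ATRA they gained 17 of 56 peaks (95.9th, 92.6th with the added matching).

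**Figure D4:**
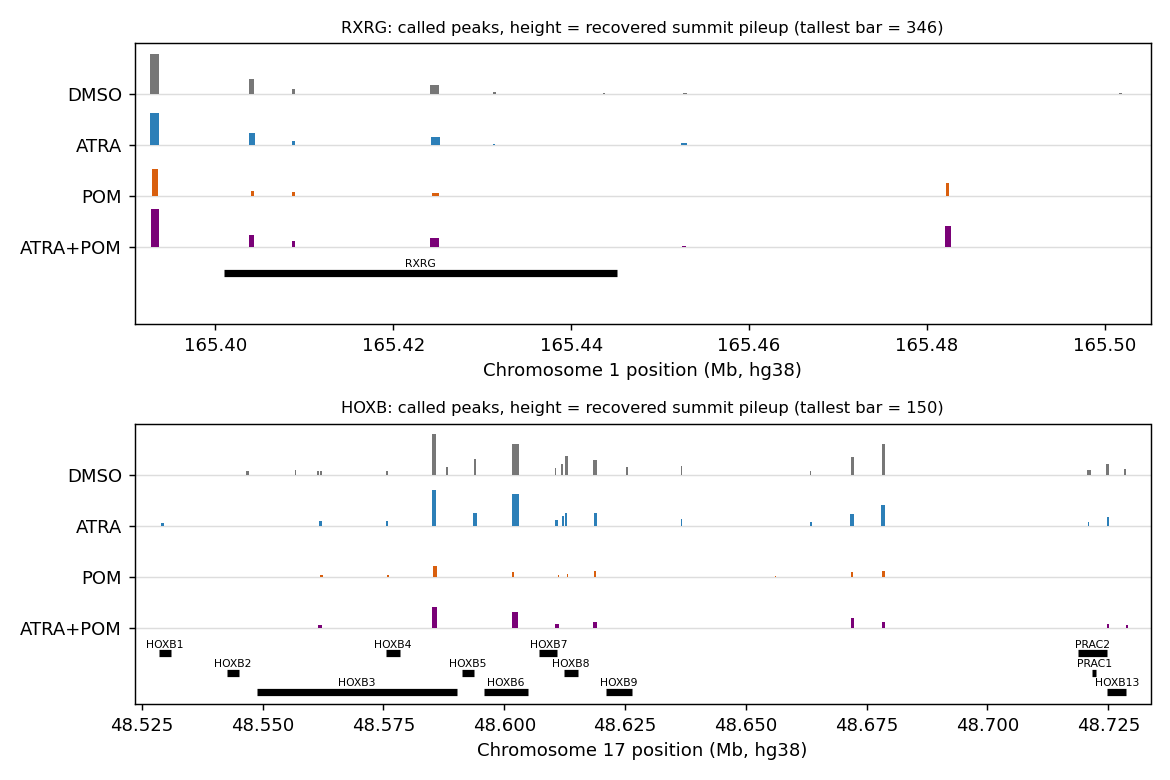
Called peaks of the 4 libraries along the RXRG region of chromosome 1 and the HOXB cluster of chromosome 17 (horizontal axis, position in Mb on hg38), with bar height for the recovered summit pileup, on 1 scale within each panel and not adjusted for depth, and black bars for protein-coding genes. The gained region beside RXRG appears in POM and ATRA+POM, and HOXB holds 21 peaks in DMSO, 16 in ATRA, 10 in POM and 9 in ATRA+POM.

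For the other lists, the losses after POM lay below the 95th percentile of matched lists. Of the DMSO peaks assigned to retinoic acid genes 72 of 208 were absent, of cereblon pathway genes 39 of 112, of interferon-stimulated genes 24 of 89, and of myeloma oncogenes and tumor suppressors 59 of 164. Plasma cell markers lost 42 of 123, B cell markers 35 of 102, T and NK cell markers 34 of 75, erythroid and megakaryocyte markers 11 of 24, and epithelial and fibroblast markers 13 of 47. Apoptosis genes lost 43 of 139, cell cycle genes 43 of 140, NF-kB genes 24 of 80, unfolded protein response genes 37 of 107, and WNT genes 49 of 144. Antigen presentation and surface target genes lost 19 of 66, chromatin regulators 62 of 176, and housekeeping genes 22 of 57. Genes of MAPK feedback and AP-1 lost 33 of 134, at the 0.055th percentile. After ATRA+POM, T and NK cell markers lost 29 of 75 (96.5th, 90.1st with the added matching) and erythroid and megakaryocyte markers 11 of 24 (98.0th, 81.6th with the added matching). Over all regions, 9 of 200 values reached the 95th percentile and 29 lay at or below the 5th, and with the added matching 3 and 25 did.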

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

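Predictions for the tests below were written before each test was run, but the shift along gene density was tested after that gradient and the simulations without it had been seen, and the expected pileups per region, the ratios between libraries not used to pick a region and the HOX counts for ATRA+POM vs ATRA were added after the results were seen.

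Several measures moved in opposite directions when an agent was added without and with the other agent, and none of these differences was tested. The number of peaks changed by -7240 when POM was added to DMSO and by 8798 when it was added to ATRA. POM and ATRA+POM had 33.6% and 62.7% of the depth of DMSO, with smallest called pileups of 4 and 7. These changes in peak number therefore cannot be told apart from depth and calling level. Covered sequence changed by -0.106 Mb when ATRA was added to DMSO and by 20.9 Mb when it was added to POM, the shallowest library. Peaks assigned to RARB changed by -5 with ATRA alone and by 1 with ATRA on POM. CD38 peaks changed by -2 with POM alone and by 1 with POM on ATRA. IKZF1 peaks changed by -2 with POM alone and 2 with POM on ATRA, and by -1 with ATRA alone and 3 with ATRA on POM.

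The strong regions gained with POM, such as those near RXRG and GOLIM4, were weighed against depth, a shift along the genome and a shared preparation. Libraries simulated at the recovered depths without an effect gave 0 strong gained regions in every draw. With the shift from gene-rich to gene-poor sequence they gave at most 3, against 461 and 508 merged regions observed. This argues against either as the whole cause only at the dispersion of DMSO and ATRA, whose log2 ratios had an SD of 0.19 beyond counting error. For pairs joining a library with POM to one without, the SD was 0.65 to 0.68, which that dispersion does not cover. For ATRA vs DMSO the simulations gave 0 strong gained regions, where 9 were observed. Region by region, 35 of 453 regions gained after POM and 0 of 504 after ATRA+POM had an expected DMSO pileup within 3 SD of the calling level, and with the shift 168 and 108 did. These are less certain, and how many of them depth and the shift account for stays open, since the simulated shift gave at most 3 only at the dispersion used. Of the 453, 89 were called in ATRA and ATRA+POM, and of the 504, 93 in ATRA and POM. Their log2 pileup ratio over ATRA had a median of 1.18 and 1.28 relative to the shift, below it in 13 and 2. For these regions this argues against the shift as the whole cause. A library preparation shared by POM and ATRA+POM cannot be told apart from a POM effect, since both predict the low spread of 0.279 between these libraries, and the labels give no batch. Base composition was not measured, and an effect of POM on chromatin stays an open hypothesis.

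The strong regions lost with POM were weighed in the same way, although only 55 of the 340 lost after POM and of the 173 lost after ATRA+POM, among them those near TPTEP2-CSNK1E and LTO1, were absent from both lists with POM. Simulation at the recovered depths gave at most 2 strong lost regions, and with the shift at most 8, against 339 and 174 merged regions observed. As for the gained regions, this argues against either as the whole cause only at the dispersion of DMSO and ATRA. For ATRA vs DMSO the simulations gave at most 1 strong lost region, where 15 were observed. However, 132 of 340 regions lost after POM had an expected pileup within 3 SD of the calling level, and 213 with the shift, while 0 and 56 of 173 did after ATRA+POM. A missing peak is a weaker sign of loss for these regions, most of all in the shallow POM library. How many losses depth and the shift account for stays open, since the simulations gave at most 8 at the dispersion used. Of the regions lost after POM, 285 were called in ATRA and ATRA+POM, and the log2 pileup ratio between these had a median of -0.81 relative to the scale of the libraries and -0.56 relative to the shift, below the shift in 246. Of the 173 regions lost after ATRA+POM, 114 were called in both POM and ATRA. Their ratio of POM over ATRA had a median of -0.34 and -0.13, below the shift in only 66. These 114 leave out the 55 regions absent from POM, so they cannot speak for the whole set. A loss common to both libraries with POM, from POM or a shared preparation, stays open for both sets, with little backing among these 114 regions.

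The loss of regions assigned to the HOXA and HOXB genes of the HOX list, which lay mostly in HOXB, was weighed against depth and the shift. Without an effect the simulations gave at most 12 lost HOX regions, against 15 merged regions observed in both comparisons with DMSO, so depth alone fell short. With the shift they reached 15 for POM vs DMSO, at most 14 of the 15 observed for ATRA+POM vs DMSO and at most 12 of the 16 observed for ATRA+POM vs ATRA. In the test of the code, libraries with 0 planted strong lost regions gave 3, against at most 2 in redraws. A count of 15 against at most 14 in 20 draws therefore decides nothing. Only the count for ATRA+POM vs ATRA, added after the results were seen, lay well above the simulated range (4 to 12). Lists matched on score and gene number left HOX at the 96.4th and 97.0th percentiles against DMSO, which by the bound set beforehand would have excluded the shift, but that matching divided each property coarsely and the simulated shift reached the observed count after POM alone. Against DMSO, the shift from gene-rich to gene-poor sequence and a specific loss around these genes therefore cannot be told apart. The count for ATRA+POM vs ATRA goes against the shift as the whole cause without excluding it. The list was singled out for its losses, and the simulations rest on a shift measured in other regions and on the dispersion of DMSO and ATRA. They also draw neighbouring regions independently, so their ranges may be too narrow for clustered genes.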

How the results depend on the processing

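Of the alternatives, leaving out peaks under 300 bp and the added matching of random lists were chosen after the results were seen. The number of strong peaks moved the strong counts by its own construction, since weaker peaks enter or leave. Gained and lost counts with 10000 and then 30000 strong peaks were 0 and 2, then 89 and 111 for ATRA vs DMSO, 72 and 2, then 1420 and 1849 for POM vs DMSO, and 78 and 7, then 1553 and 942 for ATRA+POM vs DMSO. They were 107 and 3, then 1900 and 876 for ATRA+POM vs ATRA, and 0 and 22, then 608 and 452 for ATRA+POM vs POM. When absence meant no summit within 250 bp, the counts were 626 and 633 for ATRA vs DMSO, 1491 and 1370 for POM vs DMSO, 1362 and 1057 for ATRA+POM vs DMSO, 1689 and 1135 for ATRA+POM vs ATRA, and 696 and 790 for ATRA+POM vs POM, and the cause was not tested. Without peaks under 300 bp, 13 strong lost regions were left for ATRA+POM vs POM.

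For all regions, the upper 75% of each list gave 7332 gained and 7327 lost for ATRA vs DMSO, 10086 and 16727 for POM vs DMSO, 17829 and 11605 for ATRA+POM vs DMSO, 18143 and 11949 for ATRA+POM vs ATRA, and 17696 and 4661 for ATRA+POM vs POM, with fewer peaks by construction. A reciprocal overlap of 50% gave 37034 gained and 44274 lost for POM vs DMSO and 27498 lost for ATRA+POM vs POM. The cause was not tested. Lists truncated to 69162 peaks gave 17395 gained and 17992 lost for ATRA+POM vs DMSO, 17992 and 18408 for ATRA+POM vs ATRA, and 16469 and 15035 for ATRA+POM vs POM. The excess of gained over lost regions in the full lists thus turned in the comparisons with DMSO and ATRA, as the longest list lost most peaks by construction.

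With all annotated genes, near-boundary shares were 8.61% and 18.5% for strong gained and lost regions after POM and 7.14% and 24.3% after ATRA+POM, and a 2.5 kb window gave 18.2% for those lost after POM, as more sequence counts as near. Lists at or above the 95th percentile numbered 9 over all regions against 4 over strong ones, and the cause was not tested. The other values stayed within the limits set for each: 24 of all-region counts, 29 of strong counts, 3 near-boundary shares, 4 membership patterns and 3 counts of lists. Of single list percentiles, 442 moved and 358 did not. Strong counts kept within 1.5 times under the 500 bp margin and under truncated lists. The motif alternatives (window, matching, regions) were not run. Depth limits the losses most in POM, where a summit pileup of 15 was the median. No paired analysis was possible because the labels give no replicate numbers and each result compares lists without a test.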

Other observations

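The gene families below and their tests were chosen after the data were seen, as 18 families picked by gene symbol.

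Regions called in POM and ATRA+POM but in neither DMSO nor ATRA were counted per family, and the percentiles describe families picked after these regions were seen. Cadherin genes held 36 such regions against a median of 14 in random lists matched on DMSO peaks per gene (99.9th percentile), led by CDH18 with 9, CDH12 with 7 and CDH10 with 5. Ionotropic glutamate receptor genes held 42 against 11 (100th), with 8 at GRIK2 and 6 at GRIA2. Contactins and contactin-associated proteins held 29 against 8 (100th), with 12 at CNTNAP2 and 4 at CNTN4. Teneurin and ADGRL genes held 24 against 8 (99.5th), olfactory receptor genes 40 against 26 (98.8th), protocadherin genes 17 against 8 (96.4th) and collagen genes 33 against 21 (95.3rd). In all, 8 of the 18 families reached the 95th percentile. The number of peaks at CDH18 was 11 in DMSO, 15 in ATRA, 23 in POM and 48 in ATRA+POM, and at CNTNAP2 it was 39, 37, 55 and 80. With random lists matched also on gene length and gene density, cadherins stood at the 99.8th percentile, glutamate receptors and olfactory receptors at the 100th, contactins at the 99.8th, and teneurin and ADGRL genes at the 98.7th. This matching divided length and density coarsely, so it cannot remove their influence. Among regions in DMSO and ATRA alone, cadherins (93.0th) and collagens (92.7th) were high too. Glutamate receptors (71.0th) and olfactory receptors (59.3rd) lay nearer the middle. Contactins (9.5th), protocadherins (7.8th) and teneurin and ADGRL genes (2.9th) were low.

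Other families did not stand out in this way. GABA-A receptor subunit genes held 5 such regions against 4 (57.0th percentile, or 17.2nd when matched also on length and density), and solute carrier genes 89 against 90. ZNF genes, which cluster on chromosome 19, held 59 against 81 (1.75th percentile, or 17.1st when matched also on length and density), and forkhead genes 7 against 14 (4.07th). Potassium channel genes held 66 against 39 (99.7th) and also 79 against 58 (98.9th) among regions in DMSO and ATRA alone, so they stood out on both sides. HOX genes held 14 regions in DMSO and ATRA alone against 5 (99.9th, or 99.5th when matched also on length and density), with 2 each assigned to HOXB1, HOXB9 and HOXC9. Since random lists drew scattered genes, percentiles of clustered genes such as these can be overstated.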
